A study of Mus musculus with 8 samples.

How the data were processed

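Open chromatin was measured by ATAC-seq, in which the Tn5 transposase cuts accessible DNA and attaches sequencing adapters, in primary neurons grown from the cortex of mouse embryos at day 16.5 of gestation. The 8 libraries fall into 4 conditions of 2 libraries each. Wild-type neurons (WT) and neurons in which Cre driven by the neuronal gene BAF53b deletes Brg1 (cKO) were taken without KCl (basal) or after 50 mM KCl for 1 h. KCl depolarises neurons and opens voltage-gated calcium channels. Per the labels' protocols, TTX at 1 µM and APV at 100 µM were added on day 5 in vitro to block spontaneous activity, and KCl followed on day 6. The labels name this pretreatment for depolarisation and do not state whether basal cultures received it. Each library was made from 50000 cells with 7 to 9 PCR cycles and sequenced with paired 75-bp reads, and the labels state 60 M reads for each library.

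Per the submitters' processing notes, the builds were GRCm38 and mm10, which are names of the same assembly, and Bowtie2 and MACS2 were used. Their versions and settings are not given in the sources used here. The same holds for duplicate removal, the shift of reads for the Tn5 offset, the length range of fragments taken as nucleosome-free, and how the 2 libraries of a condition were combined. The authors deposited 1 list of nucleosome-free peaks per condition, in narrowPeak layout without a header line. A list was tied to its condition by the genotype and treatment in its name, each of which matched the titles of 1 condition only. In that layout, the deposited columns hold a score, a fold over the local background at the summit (a ratio), the −log10 of the p-value and of the q-value, and the distance of the summit from the start in bp. The lowest deposited −log10 q per list lay between 1.31 and 1.51. These values per peak are the authors' own and served only to describe, rank or filter peaks within their list.

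The number of reads behind each list is not in the files, but a measure of its relative depth was recovered. A fold of (pileup + 1)/(background + 1), with the pseudocount of 1 that MACS2 uses, and the Poisson p-value give 2 equations for the fragment pileup and the local background. A whole-number pileup solved both for 100% of the peaks of each list, within 0.001 in −log10 p. The most frequent background, the floor that the caller sets from all reads, was 9.30 for WT basal, 8.24 for WT KCl, 9.47 for cKO basal and 8.36 for cKO KCl. Depth thus differed by at most 1.15 times between lists. With a median summit pileup near 30 fragments in WT KCl and 32 in WT basal, most peaks rested on few fragments, and presence in a list is a threshold call.

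Peaks on chromosomes 1 to 19, X and Y were used, and 5 peaks per list on the mitochondrial chromosome were left out. Peaks of 2 lists were shared when they overlapped by at least 1 bp. The 4 lists were merged into regions by the same rule. Genes came from the RefSeq gene table of GRCm38.p6, the build of the files, which gives the start and end of 21883 protein-coding genes without strand, transcripts or exons. The design had named transcript starts. In their place a site was called a gene end when it lay within 1 kb of either annotated end of a protein-coding gene, and other sites were called intragenic or intergenic. Exon, intron and UTR classes were not analysed here. The search for 24 consensus motifs needs the genome sequence and was not analysed here either. No columns of unmatched samples were present (0).

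With 1 list per condition there is no spread between replicates, so no test compares the conditions. Shares carry exact 95% Clopper-Pearson intervals, which cover counting error only. Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 8 tests compared the gene-end share of regions in 1 list with that of shared regions, and it compares lists rather than conditions. For the 3 ways of setting 2 lists against the other 2, the product of the counts of the complementary patterns is equal across splits when lists differ in overall sensitivity alone. This assumes that a list's sensitivity shifts the log odds of detection equally for every region, which was not tested for these peak calls. Under this assumption, the log2 ratio of the geometric mean of the genotype or KCl split to that of the crossed split was computed, with its counting error. This ratio was chosen after the data were seen. The design also had an expected overlap of independent lists, which is left out because regions open in no list are not counted and every pattern then falls below it. For 17 gene lists with 289 entries, all matched by symbol, the net change was the number of regions in the second list minus the first within 50 kb of the gene body. The list's median was placed among 10000 random lists of the same size, matched on the number of regions per gene up to 15, as a percentile that describes these peak lists. Neighbouring genes of a list, such as those of a Hox cluster, share regions, which random lists do not copy. The percentiles were therefore repeated with 1 gene per cluster, an alternative chosen after the data were seen, which left 14 of 22 developmental genes and 14 of 16 inhibitory neuron genes.

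The gene lists, comparisons, thresholds and alternatives were chosen before the data were examined. So was the rule for named peaks. It takes, per comparison and direction, the 5 gene-end and 5 other peaks with the highest fold among peaks with −log10 q of at least 10 and no peak of the partner list within 1 kb, on chromosomes 1 to 19 and X, with 1 peak per gene and the nearest protein-coding gene as name. It adds the targeted gene, the 5 regions of highest fold for each 2-list pattern, every rapid response gene, and 2 to 4 genes of each other list with the largest net change. The latter are given for every list in the comparison of WT basal with cKO basal and for a part of the lists elsewhere, chosen after their values were seen, and some genes the rule selects are not reported here. Alternatives were a 50% reciprocal overlap, a gap of 500 bp, −log10 q of at least 5 or 10, equal list lengths, equal depth, gene ends within 2 kb, windows of 10 or 100 kb and the list mean.

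The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and were tested on simulated data. The pileup was recovered for 99.98% of 5000 simulated peaks. In 30751 simulated regions that differed by list sensitivity alone, the log2 ratio of the genotype split to the crossed split was -0.02 with a standard error of 0.05. With 500 regions planted per genotype among 31326, it was 0.57. The simulated lists were drawn under the log-odds assumption, so these values check the calculation and not whether peak calls meet the assumption. Of 200 unchanged simulated gene lists of 20 genes, 0% lay beyond the 95% range, and 79% of 100 lists were found low when each gene lost 1 more region. The percentile of a median was thus a strict measure in this simulation. Its windows were narrower than the real ones, and every gene of a list lost the same number, so the 79% does not carry over. Among the real lists, developmental genes had a median of -2 in WT basal against cKO basal, with -1 in random lists, and stood at the 12.3rd percentile. A count of 0 lists beyond the range therefore does not exclude changes of this size.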

Results

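Peak lists of nucleosome-free ATAC-seq fragments described open chromatin in cultured mouse cortical neurons under 4 conditions. WT neurons and cKO neurons, which delete Brg1 (Smarca4), the ATPase of the BAF chromatin remodelling complex, were compared without KCl and after depolarisation with 50 mM KCl for 1 h. Each condition had 2 libraries and 1 deposited list, so every value below stands for 1 list without replicate error. The WT basal list held 34061 peaks over 11.3 Mb, WT KCl 20229 over 6.93 Mb, cKO basal 20484 over 6.87 Mb and cKO KCl 25690 over 9.15 Mb. Median widths were 271, 279, 275 and 287 bp. Background pileup, a measure of depth if fragment lengths were equal, was 9.30, 8.24, 9.47 and 8.36 fragments in the same order. By this measure cKO basal was deepest, and it had fewer peaks than either WT basal or cKO KCl.

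Smarca4, on chromosome 9, carried a peak at its lower-coordinate end (21615669 to 21616724, GRCm38) in all 4 lists, with a fold over background of 4.89 in WT basal, 5.32 in WT KCl, 5.21 in cKO basal and 5.62 in cKO KCl. This site is not known to lie in the deleted part, so it does not check the genotype labels.

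The shared part of the lists was dominated by gene ends. The 4 lists merged into 62023 regions, of which 7197 (11.6%) had a peak in all 4 lists and 44267 (71.4%) in 1 list. Of the regions in all 4 lists, 75.6% lay at a gene end, as at Jun (chromosome 4, 95051953 to 95052874), Dusp1 (chromosome 17, 26507967 to 26508941) and Btg2 (chromosome 1, 134079033 to 134079452). Of the regions in WT basal alone, 9.96% did. Gene ends took 31.4% of WT basal peaks (95% interval 30.9 to 31.9), 42.7% of WT KCl, 41.4% of cKO basal and 39.2% of cKO KCl peaks, against 5.97 to 6.56% after shifting the peaks by 100 kb. Intragenic sites took 37.0, 31.8, 33.0 and 34.1%, and intergenic sites the rest.

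**Figure D1:**
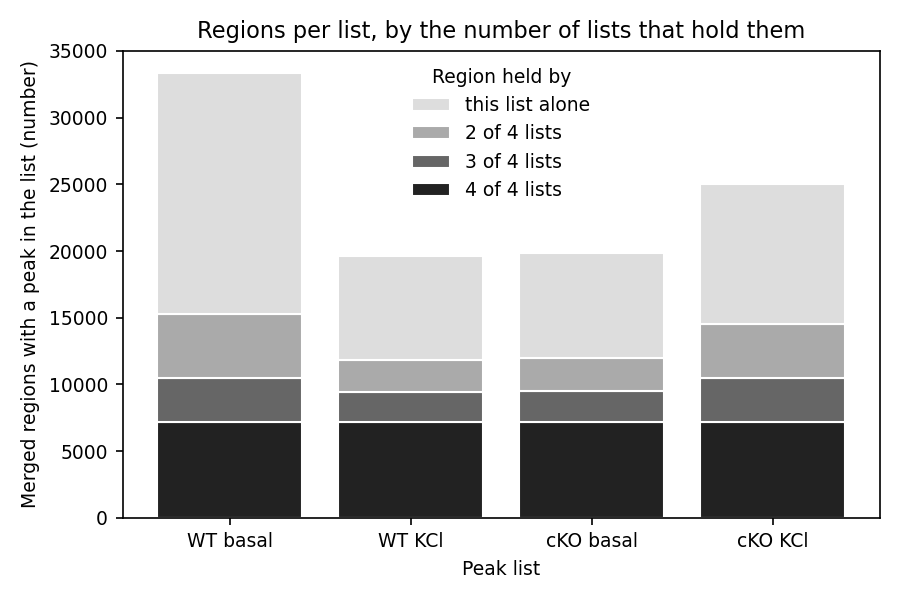
Number of merged regions (vertical axis) with a peak in each of the 4 peak lists (horizontal axis), shaded by how many lists hold the region. The 7197 regions held by all 4 lists form the base of each bar, and WT basal has the most regions of its own, 18080.

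The comparison of WT basal with cKO basal asked which sites are open in neurons with and without Brg1 when no KCl is added. Among the strongest sites of WT basal with no peak in cKO basal were gene ends of Parp2, a sensor of DNA strand breaks (fold 7.22, chromosome 14, 50807497 to 50808041), Lurap1l (6.31), Lypla1, an acyl-protein thioesterase (5.73), Mettl14, part of the RNA adenosine methyltransferase (5.73), and the X-linked scaffold gene Mpp1 (5.63). Sites away from gene ends lay nearest to Mrpl39 (5.44, 676 kb away), inside Zswim6 (5.34) and Vps50 (5.15), and nearest to Arl4a and the stress gene Sesn2 (5.15 each). In the reverse direction cKO basal had gene-end peaks absent from WT basal at Tmem216, a gene of the ciliary transition zone (4.77), Ccdc173 (4.49), Plekhm3 (4.39), Dpyd, the first enzyme of pyrimidine breakdown (4.30), and A430033K04Rik (4.30). The strongest cKO basal site away from gene ends was nearest to 4933412E24Rik (6.11, chromosome 15, 60141737 to 60142056) and was also present in cKO KCl. Others lay nearest to Sfi1 (5.39) and Alkbh8 (4.49), both near the first assembled base of their chromosome, and to Nemf (4.68) and Nxpe2 (4.49).

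Of WT basal peaks, 23413 (68.7%, 95% interval 68.2 to 69.2) had no overlapping peak in cKO basal, and 9746 of cKO basal peaks (47.6%, 46.9 to 48.3) had none in WT basal. These unmatched peaks were mostly weak. Among the 10% of WT basal peaks with the highest fold, 4.32% were absent from cKO basal, against 89.0% among the 10% with the lowest fold. For cKO basal peaks the values were 1.07% and 75.4%. At gene ends 36.0% of WT basal peaks and 18.97% of cKO basal peaks were unmatched, and away from them 83.7% and 67.8%. All 10 named WT basal sites had a peak in cKO KCl, and 6 of them had one in WT KCl as well.

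Genes of the fixed lists followed the shorter cKO basal list. Of 20 rapid response genes, which neurons transcribe within minutes of activity, 15 had fewer regions within 50 kb in cKO basal, with Nr4a1 at 7 and 3, Egr2 at 4 and 1, and Btg2 at 5 and 2. The 3 with more were Egr1 (3 and 5), Maff (2 and 4) and Ccn1 (2 and 3), and rapid response genes with a gene-end peak were 7 in WT basal and 9 in cKO basal, with Egr1 and Maff in cKO basal alone. Of 20 excitatory neuron genes 12 had fewer, led by Sox5, a transcription factor of deep-layer neurons (22 and 5), Foxp1 (13 and 6) and Nfib (8 and 2). Of 22 developmental genes that are silent in cortex, 20 had fewer, including Hoxb4 (7 and 1) and Tbx5 (7 and 2), and of 25 BAF subunit genes 19 had fewer, including Dpf3 (15 and 3), Smarcc1 (14 and 8) and Bcl11a (8 and 2). Genes of 1 Hox cluster share regions and are not separate observations. Synapse genes (Grin2b, 10 and 4, and Shank2, 13 and 8), ion channel genes (Cacna1a, 10 and 4, and Scn8a, 6 and 3) and activity signalling genes (Cacna1c, 13 and 6, and Camk2b, 9 and 3) did likewise in 14 of 20, 9 of 18 and 13 of 21 cases. The largest net changes elsewhere were at Atf3 (5 and 1) and Crem (5 and 2) among delayed response genes, Nxph1 (7 and 2) and Calb2 (6 and 3) among inhibitory neuron genes, L1cam (6 and 1) and Ntn1 (10 and 6) among axon guidance genes, and Nes (9 and 3) and Notch1 (8 and 3) among progenitor genes. In the cell cycle, astrocyte and oligodendrocyte lists they were at Tyms (5 and 0) and Mcm5 (7 and 3), Aldh1l1 (6 and 2) and Aldoc (6 and 3), and Olig2 (9 and 4) and Pdgfra (6 and 1). In the microglia, vascular and housekeeping lists, genes with large net changes included Spi1 and Tyrobp (5 and 1 each), Flt1 (8 and 2) and Cldn5 (5 and 2), and Eef1a1 (7 and 1) and Actb (6 and 4). Of 10 microglia genes 7 had fewer and 2 had more, Itgam (0 and 4) and Tmem119 (1 and 4). None of the 17 lists had a median net change beyond the 95% range of matched random lists (0 lists). Rapid response genes stood at the 21.4th percentile, delayed response genes at 40.9, excitatory neuron genes at 68.8, synapse genes at 87.7, ion channel genes at 92.3 and developmental genes at 12.3. The developmental genes passed below that range with a window of 100 kb (0.78) or with the list mean (2.3), but not with 1 gene per cluster of neighbouring genes (55.5 and 12.9).

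**Figure D2:**
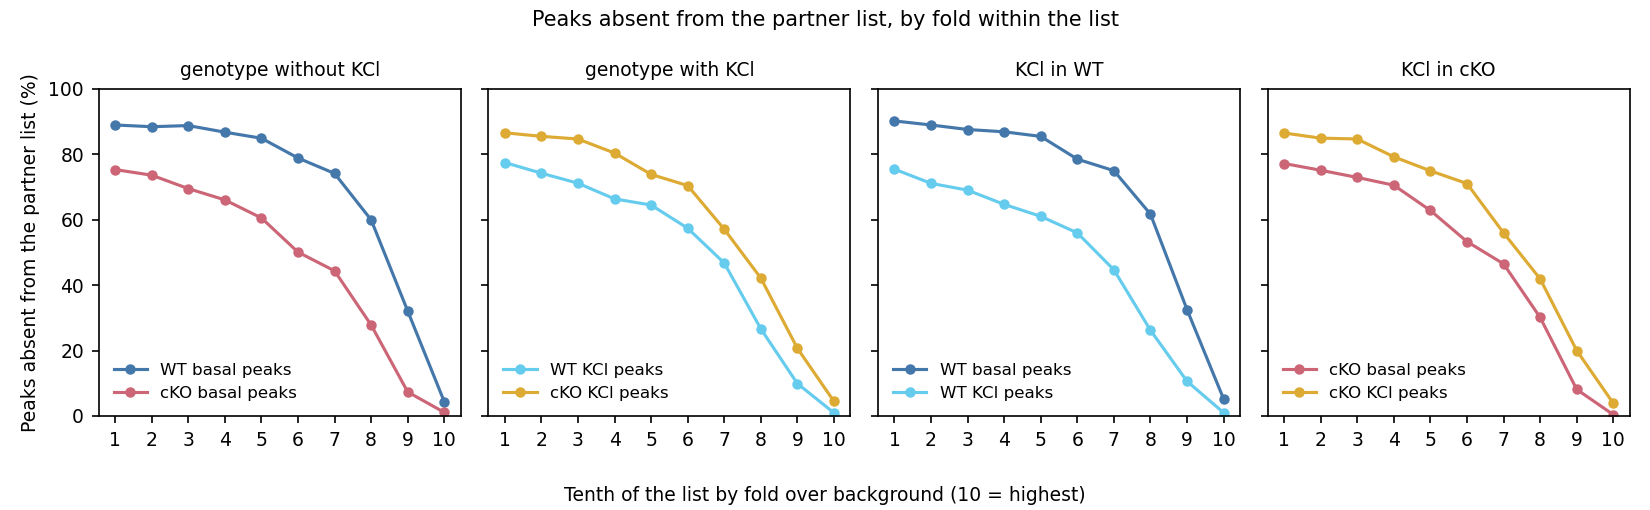
Percent of the peaks of a list with no overlapping peak in the partner list (vertical axis) by position in the list when ranked by fold over background into 10 equal parts, 10 being the highest (horizontal axis), in 1 panel per comparison with 1 line per list. In all 4 panels the share is between 0.39 and 5.17% in part 10.

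The comparison of WT KCl with cKO KCl asked the same of depolarised neurons. Here the longer list was that of cKO. Its strongest gene-end peaks absent from WT KCl lay at Rad1, a subunit of a DNA damage checkpoint clamp (fold 6.95, chromosome 15, 10485824 to 10486198), Ndufaf7, an assembly factor of respiratory complex I (6.05), Csgalnact1, which acts in chondroitin sulfate synthesis (5.98), Plekhg1 (5.80) and Actr6 (5.34). Away from gene ends they lay inside St7 (6.95), inside Dnm3, a dynamin (6.31), and nearest to the chromatin remodeller gene Chd2 (6.61), Akr1e1 (6.52) and Spin2f (6.52). In WT KCl and not in cKO KCl were gene-end peaks of Zfp948 (4.87), Pecr, a peroxisomal enoyl-CoA reductase (4.78), Asmt (4.55), the complex I subunit Ndufa12 (4.54) and Scamp2 (4.44). Peaks inside Igsf11, an adhesion molecule gene (4.84), Trim50 (4.49) and Nfyc, a subunit of the CCAAT-binding factor (4.44), and nearest to Gm51591 (4.55) and Sptssa (4.33) were absent from cKO KCl too.

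Of WT KCl peaks 10023 (49.5%) were unmatched in cKO KCl, and of cKO KCl peaks 15567 (60.6%) were unmatched in WT KCl. Among the 10% of highest fold the shares were 0.939% and 4.44%, and among the 10% of lowest fold 77.5% and 86.6%. At gene ends they were 19.03% and 31.1%. Of the 10 named cKO KCl sites, 9 had a peak in both basal lists and were thus missing from WT KCl alone.

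Rapid response genes had more regions in cKO KCl for 11 of 20 genes and fewer for 5, with Ier2 and Junb at 3 in WT KCl and 7 in cKO KCl and Egr1 at 2 and 5. Neural progenitor genes had more for 11 of 16, including Notch1 (1 and 7) and Nes (4 and 8), and stood at the 97.1st percentile. Cell cycle genes had more for 10 of 14, including Mcm2 (3 and 9) and Top2a (2 and 5), at the 95.6th percentile. Synapse genes had more for 13 of 20, with Grin2a at 3 and 11 and the presynaptic scaffold gene Bsn at 2 and 9 (percentile 64.4), and axon guidance genes for 16 of 20, with Robo1 at 3 and 6 (76.8). None of the 17 lists lay beyond the random range (0 lists). With the list mean, the progenitor genes (99.91) and cell cycle genes (98.9) did, and with a window of 10 kb the delayed response (99.2) and synapse genes (99.4).

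Depolarisation of WT neurons was examined by comparing WT basal with WT KCl. Of the rapid response genes, Junb, Egr1, Gadd45b and Maff had a gene-end peak in WT KCl and none in WT basal, while Arc and Ier2 had one in WT basal and none in WT KCl. Fos kept a gene-end peak in both lists (3.50 and 2.88, chromosome 12, 85473525 to 85474220), as did Jun, Dusp1, Btg2 and Klf4. The Egr1 site without a WT basal peak (chromosome 18, 34860905 to 34861409) lay beside another merged region, 34859770 to 34860749, in which each of the 4 lists had a peak, that of WT basal ending beyond the 1 kb limit. The number of rapid response genes with a gene-end peak was 7 of 20 in WT basal (35%, 95% interval 15.4 to 59.2) and 9 in WT KCl (45%, 23.1 to 68.5). These intervals overlap widely. Among all 21883 genes it was 10179 and 8706.

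The strongest WT basal sites absent from WT KCl were again gene ends of Rad1 (7.58) and Plekhg1 (5.54), together with those of Dlst, a subunit of the 2-oxoglutarate dehydrogenase complex (5.62), the histone demethylase gene Kdm5c (5.57) and Dhx30 (5.52). Away from gene ends they lay nearest to Chd2 (6.60), Mpp7 (6.12) and Ndfip2 (5.44), inside the BAF subunit gene Smarcc1 (5.83) and inside Ctnnd2, which encodes delta-catenin (5.44). All 10 had a peak in both cKO lists. WT KCl had gene-end peaks absent from WT basal at E430018J23Rik (4.73), Klhdc4 (4.66), Garre1 (4.60), Tmem199 (4.55) and Abhd6, a hydrolase of endocannabinoids (4.46), and other peaks inside Plag1 (4.55), Trim50 (4.49), Ctnnd1 (4.44) and Cntrl (4.33) and nearest to Sptssa (4.33). Of WT basal peaks 23576 (69.2%) were unmatched in WT KCl and of WT KCl peaks 9707 (48.0%) in WT basal, at 5.17% and 0.989% among the 10% of highest fold and 90.2% and 75.5% among the 10% of lowest.

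Near rapid response genes WT KCl had fewer regions for 12 of 20 genes, including Ier2 (7 and 3), Arc (5 and 1) and Klf4 (4 and 1), and more for 2 (percentile 74.9). Delayed response genes had fewer for 13 of 20, including Per1 (9 and 5) and Crem (5 and 2), while Bdnf had 2 and 3 (39.7). Cell cycle genes had fewer for 13 of 14, including Mcm5 (7 and 2) and Tyms (5 and 0), at the 3.07th percentile. None of the 17 lists lay beyond the random range (0 lists). With the list mean the housekeeping genes did at 99.045. The developmental genes did at 0.095 with the list mean and at 0.225 with a window of 100 kb, values that the Hox clusters overstate: with 1 gene per cluster they were 0.595 and 2.98.

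In cKO neurons KCl went with a longer list. Junb, Gadd45b, Egr3 and Egr4 had a gene-end peak in cKO KCl and none in cKO basal, and Klf4 the reverse, so that rapid response genes with a gene-end peak numbered 9 in cKO basal and 12 in cKO KCl, against 8495 and 9892 among all genes. Within 50 kb, Egr2 had 1 region in cKO basal and 6 in cKO KCl, Junb 3 and 7, Nr4a1 3 and 6, and Bdnf, the neurotrophin gene, 0 and 5. More regions in cKO KCl were found for 13 of 20 rapid response genes (percentile 72.4), 12 of 20 delayed response genes (90.1) and 11 of 16 progenitor genes, including Nes (3 and 8) and Notch1 (3 and 7), at the 97.2nd percentile. None of the 17 lists lay beyond the random range (0 lists). With the list mean the progenitor genes (98.1) and the oligodendrocyte genes (2.31, and 4.14 with Olig1 and Olig2 counted as 1 gene) did, the latter also at equal list lengths (0.51), and with a window of 100 kb the vascular genes (98.5).

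The strongest cKO KCl sites absent from cKO basal were gene ends of Mettl14 (5.88), AW146154 (5.88), Palb2, a partner of Brca2 in DNA repair (5.77), Actr6 (5.34) and Pnpt1 (5.34). Away from gene ends they lay nearest to the peroxisome gene Pex2 (6.09), Arl4a (5.56) and Rad23b (5.56), inside Sox5 (6.07, chromosome 6, 144056736 to 144057511) and inside Clcn3, an endosomal chloride exchanger gene (5.98). In cKO basal and not in cKO KCl were gene ends of Zscan25 (4.22), Anp32b (3.99), Rdm1 (3.95), the BAF subunit gene Dpf2 (3.87) and the condensin gene Ncapd3 (3.75), and sites nearest to Nemf (4.68), Nxpe2 (4.49) and Gm51591 (4.11) and inside Tbc1d5 (4.20) and Clstn2 (4.19). Of cKO basal peaks 10184 (49.7%) were unmatched in cKO KCl and of cKO KCl peaks 15498 (60.3%) in cKO basal, at 0.390% and 3.85% among the 10% of highest fold and 77.2% and 86.5% among the 10% of lowest.

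Comparing the KCl response of the 2 genotypes, 835 regions had a peak in both KCl lists and in neither basal list. They included 6 within 50 kb of rapid response genes: 2 at Junb (chromosome 8, 84978580 to 84979024 at the gene end and 84990355 to 84990750, 11.8 kb beyond it), the gene end of Gadd45b (chromosome 10, 80929871 to 80930095), an intragenic site of Nr4a1 (chromosome 15, 101266614 to 101266958), a site 37.9 kb beyond Npas4 (chromosome 19, 5041161 to 5041573) and a site 32.5 kb from Ccn1 (chromosome 3, 145614366 to 145614612). Folds of these 6 regions were 2.53 to 3.38 in WT KCl (list median 3.03) and 2.28 to 3.02 in cKO KCl (list median 3.08), so they were not among the strong peaks. Sites of Fos at 85454945 to 85455692 and 85485824 to 85486321 on chromosome 12 and the gene ends of Fos, Jun, Dusp1 and Btg2 had a peak in all 4 lists. Fosb had 8, 7, 6 and 7 regions within 50 kb in WT basal, WT KCl, cKO basal and cKO KCl, Amigo3 2, 1, 1 and 3, and Fbxo33 2, 2, 1 and 1. The Arc gene end (chromosome 15, 74672435 to 74672830) had one in all lists except WT KCl.

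**Figure D3:**
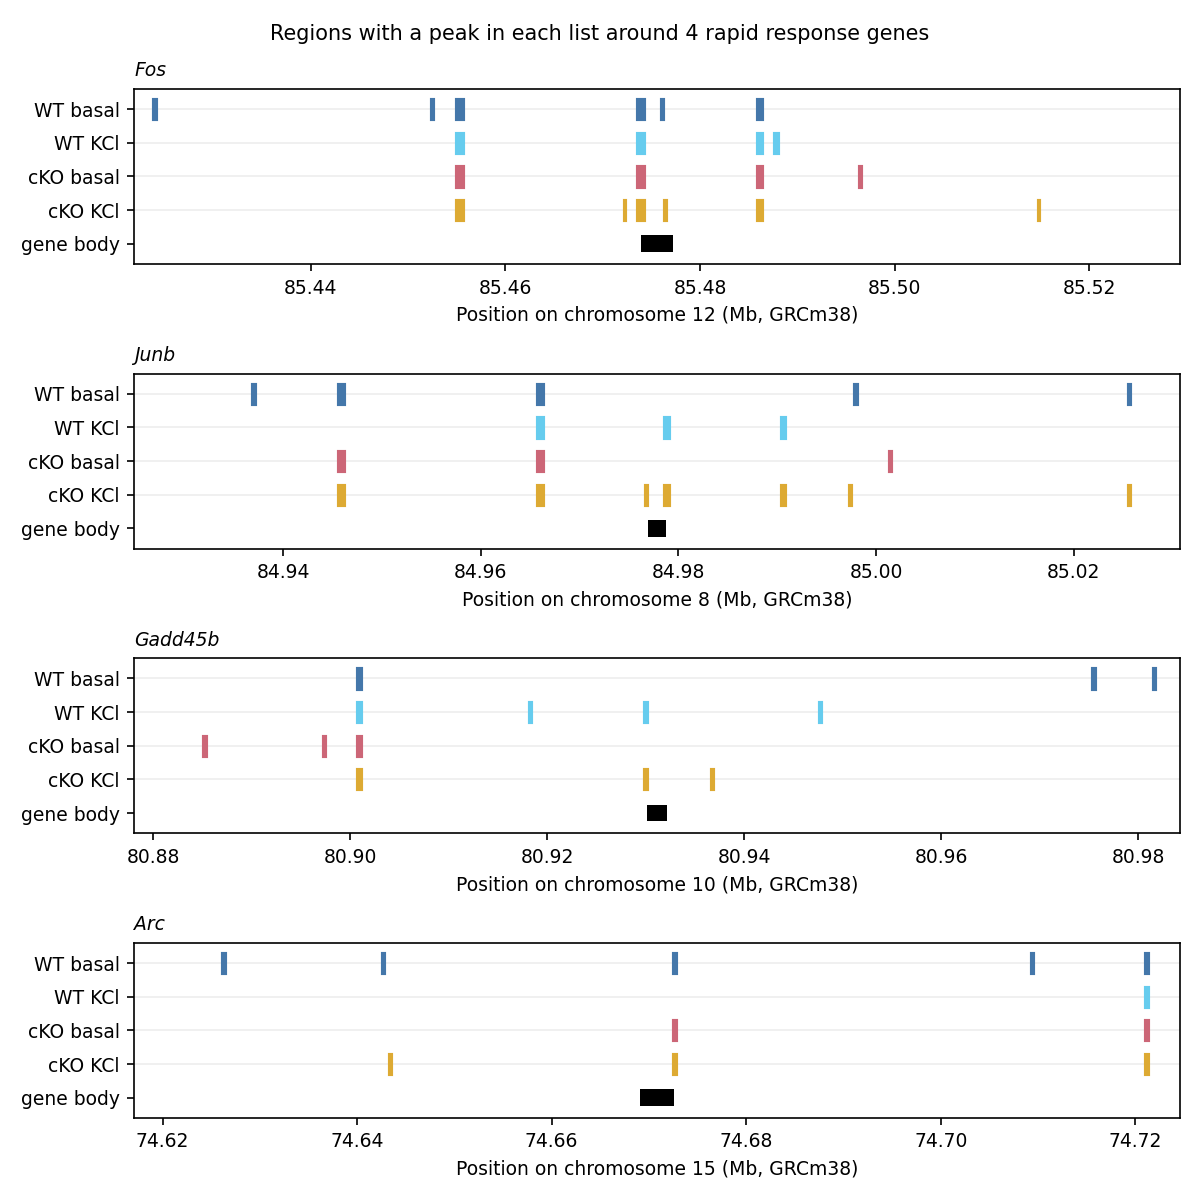
Merged regions with a peak in each list (coloured marks, 1 row per list) and the gene body (black) within 52 kb of Fos, Junb, Gadd45b and Arc, by position in Mb of GRCm38. The gene ends of Junb and Gadd45b carry a mark in both KCl rows and in neither basal row, and that of Fos carries a mark in all 4 rows.

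In WT, 9455 regions were present only after KCl and 23176 only before, and 10173 in both lists. In cKO these numbers were 15142, 9964 and 9906. Besides the 835 regions present only after KCl in both genotypes, 1217 were present only before KCl in both, and 2391 were present before KCl in WT and after KCl in cKO alone. Of the regions that WT neurons showed only after KCl, 13.2% had a peak in cKO KCl and 8.93% in cKO basal. Of those WT neurons showed only before KCl, 16.7% and 11.7% did, so both kinds were found more often in the longer cKO KCl list.

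Regions that followed genotype in both treatments were few. Both WT lists and neither cKO list held 1155 regions, led by sites inside the potassium channel gene Kcnj6 (fold 4.86 in WT basal), Igsf11 (4.84 in WT KCl) and Nfyc (4.44), and at the gene ends of Scamp2 (4.44) and Ino80d (4.39). Both cKO lists alone held 808, led by sites nearest to 4933412E24Rik (6.11 in cKO basal), Mtmr6 (5.02 in cKO KCl), Rps12 (4.92), Ttc39b and Cdkn2b (4.81 each). Both basal lists alone held 1217, led by sites nearest to Arl4d (4.77), Mppe1 (4.55), Nova1 (4.37, 457 kb away), Sfmbt2 (4.18, 193 kb away) and Tbxas1 (4.18, inside Hipk2). Among the 835 of both KCl lists, the highest folds were at gene ends of AW146154 (5.88), Zfp101 (5.34), Rbm18 and Spg20 and inside Cttnbp2 (4.81 each). The crossed patterns, which neither factor defines, held 2391 regions in WT basal with cKO KCl, led by sites nearest to Rad23b (5.56) and inside Wls (5.45), with Mrpl39 (5.44), Actr6 and Cd209a (5.34 each), and 431 in WT KCl with cKO basal, led by sites nearest to Nemf (4.68) and Tafa2 (4.39), with Pdcd6ip (4.22), Fam186a and Olfr646 (4.11 each). Geometric means of the paired patterns were 966 for genotype, 1008 for KCl and 1015 for the crossed split. The log2 ratio to the crossed split was -0.07 for genotype (95% counting interval -0.17 to 0.03) and -0.01 for KCl (-0.11 to 0.09). No excess of regions by genotype or by KCl over the crossed split was detected. The crossed split is not a neutral reference, since a KCl response that differs between genotypes would enlarge it. Regions that follow genotype or KCl are therefore not excluded.

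**Figure D4:**
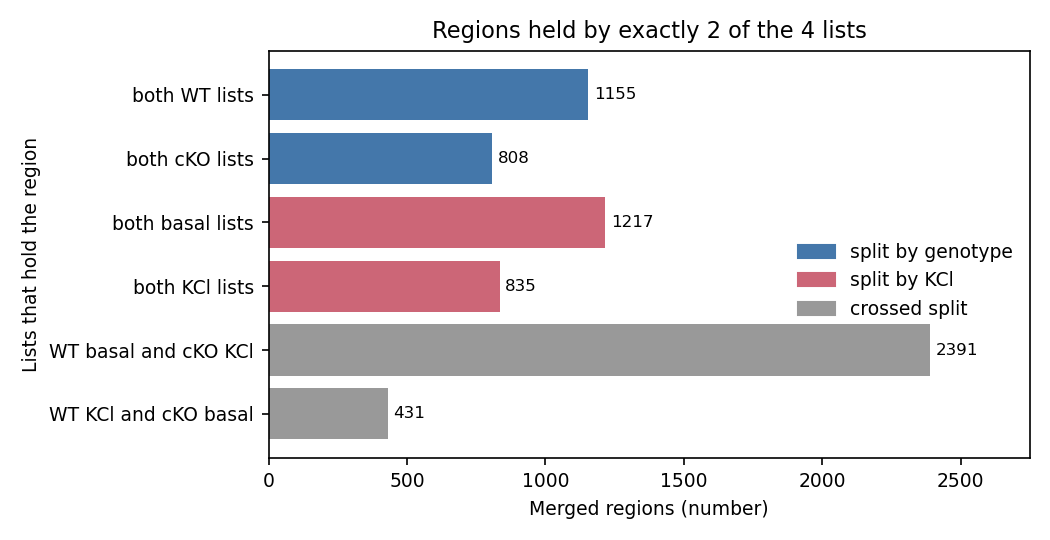
Number of merged regions (horizontal axis) held by exactly 2 of the 4 lists, for each pair of lists (vertical axis), coloured by the split the pair belongs to. The 2 pairs of the crossed split hold the most and the fewest regions, 2391 and 431.

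Shared regions lay at gene ends more often than unshared ones in every comparison. Of regions shared by WT basal and cKO basal 64.4% lay at a gene end, and of those in WT basal or cKO basal alone 15.5% and 15.4%. Across the 4 comparisons the share was 64.4 to 68.6% for shared regions and at most 20.3% for the others. Odds ratios lay between 0.0838 for WT KCl against cKO KCl and 0.127 for cKO KCl against cKO basal (Fisher's exact test, two-sided, adjusted p at or below 1e-300, the smallest value written, for all 8). This test compares regions of the lists, not the conditions. It did not hold peak strength constant. WT basal peaks shared with cKO basal had a median fold of 3.54, and unmatched ones 2.72. A part of peak strength in these odds ratios is thus not excluded.

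Among all protein-coding genes 46.5% had a gene-end peak in WT basal, 39.8% in WT KCl, 38.8% in cKO basal and 45.2% in cKO KCl. The 95% intervals of the excitatory neuron genes included these shares (36.1 to 80.9% in WT basal), so excitatory neuron genes were not set apart from all genes. Microglia genes were, with an interval of 0 to 30.8% in each list, below the share of all genes. The interval of vascular genes lay below that share in both WT lists (0.211 to 38.5%) but not in the cKO lists (5.49 to 57.2%). That of BAF subunit genes lay above it in all 4 lists, and that of housekeeping genes in all but cKO KCl. Progenitor genes lay above it in WT basal and cKO KCl (lower limits 47.6 and 61.7%), and synapse genes in cKO basal and cKO KCl (40.8 and 45.7%). Developmental genes lay below it in cKO KCl (upper limit 40.3%). In the same order, 12, 10, 12 and 12 of 20 excitatory neuron genes had one, and 10, 5, 7 and 10 of 16 inhibitory neuron genes, with Gad1, a GABA-synthesising enzyme gene, present in cKO KCl alone. Synapse genes numbered 13, 12, 13 and 14 of 20, ion channel genes 11, 6, 10 and 9 of 18, axon guidance genes 13, 12, 10 and 13 of 20, activity signalling genes 11, 10, 11 and 14 of 21, and delayed response genes 14, 11, 9 and 12 of 20. Progenitor genes numbered 12, 8, 8 and 14 of 16, with Hes5, Notch1 and Sox3 marked in WT basal and cKO KCl only, and cell cycle genes 9, 7, 9 and 9 of 14. Astrocyte genes numbered 7, 3, 3 and 3 of 10, with Gfap, Aldh1l1, Slc1a3 and S100b marked in WT basal only, oligodendrocyte genes 4, 2, 3 and 2 of 10, vascular genes 1, 1, 3 and 3 of 12, and microglia genes 0 of 10 in each list. BAF subunit genes numbered 19, 18, 18 and 20 of 25, housekeeping genes 12, 11, 11 and 11 of 15, and developmental genes that are silent in cortex 8, 4, 5 and 4 of 22.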

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

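The depth and detection comparisons in this part, and the reading of the crossed split, were chosen after the result was seen.

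The KCl list was shorter than the basal list in WT and longer in cKO. KCl minus basal, the number of peaks differed by -13832 in WT (34061 and 20229) and by 5206 in cKO (20484 and 25690). For peaks with −log10 q of at least 10 the differences were -2431 in WT and 2261 in cKO. Each group is 1 list, and the difference was not tested. Each list also held 5 peaks on the mitochondrial chromosome, outside all comparisons, with a highest fold of 2.01 in WT basal and 2.07 in WT KCl.

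Depth as read from the background, which assumes equal fragment lengths, does not alone account for both directions. In cKO the longer list had the lower background (cKO KCl minus cKO basal, -1.12 fragments of pileup). In WT the longer list was also the deeper one (background 9.30 and 8.24), so a part for depth there is not excluded. Of the strongest 10% of peaks at most 5.17% were absent from the partner list, against 75.5 to 90.2% of the weakest 10%, but the shorter lists showed this contrast as well as the longer ones, so it cannot single out a difference in how well whole lists detect sites. An opposite response to KCl in the 2 genotypes stays open too: the log2 ratio of the KCl split to the crossed split was -0.0101 (-0.11 to 0.09), but -0.12 (-0.22 to -0.03) at equal list lengths. With 1 list per condition, library and condition cannot be told apart.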

How the results depend on the processing

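No paired analysis was possible because each condition has 1 list and no values per library, so leaving out a replicate was not possible either, and the motif alternatives were not run. Equal depth left 34046 of 34061 WT basal peaks and 20472 of 20484 cKO basal peaks, so it tests little, and no result it was applied to moved. For the main results, 120 values under alternatives stayed within the interval, or for counts within 1.5 times, and 80 moved. For single gene lists 592 values stayed, 13 percentiles passed the random range and 7 counts moved. Within 2 kb of a gene end, rapid response genes with a peak were 12 in WT basal and 14 in WT KCl, and microglia genes 1 in WT KCl, 2 in cKO basal and 1 in cKO KCl. The odds ratios of gene ends kept their direction and their side of the threshold under all alternatives run. Weak peaks limit the overlap shares, since a threshold decides which of them enter a list.

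Shares of unmatched peaks are given in the order WT basal against cKO basal and the reverse, WT KCl against cKO KCl and the reverse, WT basal against WT KCl and the reverse, cKO basal against cKO KCl and the reverse. They were 75.9, 60.0, 61.8, 69.9, 76.7, 60.7, 61.7 and 69.5% with a 50% reciprocal overlap. They were 64.6, 42.8, 45.4, 56.3, 65.3, 43.4, 45.5 and 55.9% with a gap of 500 bp. They were 54.7, 27.8, 29.0, 51.7, 54.9, 30.0, 27.1 and 51.6% at −log10 q of at least 5, and 49.0, 13.7, 14.2, 55.5, 54.1, 13.9, 13.5 and 50.2% at 10. They were 54.3, 53.4, 52.2, 52.8, 54.9, 54.2, 51.8 and 52.6% at equal lengths. The −log10 q cuts were applied to every list, here and in the counts below, so a partner peak under the cut counted as absent. Against the full cKO basal list, 4.32% of the 10% of WT basal peaks with the highest fold were unmatched. Stricter lists hold fewer and stronger peaks by construction, and the causes of the other shifts were not tested.

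At −log10 q of at least 5 the 2-list patterns held 347 regions (both WT), 381 (both cKO), 322 (both basal), 424 (both KCl), 1400 (WT basal and cKO KCl) and 110 (WT KCl and cKO basal), and at 10 they held 135, 146, 148, 121, 977 and 20. At equal lengths they held 733, 842, 745, 885, 1278 and 613, so that both cKO exceeded both WT and both KCl exceeded both basal, unlike in the full lists but as at −log10 q of at least 5. The log2 ratio to the crossed split at equal lengths was -0.17 for genotype (-0.27 to -0.07) and -0.12 for KCl (-0.22 to -0.03), below 0. For genotype it was also below 0 with a 50% reciprocal overlap, at -0.13 (-0.23 to -0.04), and with a gap of 500 bp, at -0.12 (-0.22 to -0.03). In WT 2627 regions were present only after KCl and 7561 only before at −log10 q of at least 5, and in cKO 6718 and 2339. At 10 these were 382, 2787, 2660 and 412. At equal lengths 10704 regions in WT were present only after KCl and 10861 only before, and in cKO 10376 and 10274, near equality that lists of the same length bring about by construction. The regions present after KCl alone, and before KCl alone, in both genotypes are the both KCl and both basal patterns.

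The number of gene lists beyond the random range, 0 of 17 in each comparison, became 1 for genotype without KCl with a window of 100 kb and with the mean, 2 for genotype with KCl with a window of 10 kb and with the mean, 1 and 2 for KCl in WT with a window of 100 kb and with the mean, and 1, 2 and 1 for KCl in cKO with a window of 100 kb, with the mean and at equal lengths. With 1 gene per cluster, chosen after the data were seen, the numbers were 0 of 17 again in each comparison, and with the mean 0, 2, 2 and 1. In the same order they were 0, 2, 0 and 0 with a window of 10 kb, and 0, 0, 0 and 1 with a window of 100 kb. The cause was not tested, though the mean moves with single genes and the median of whole numbers hardly does.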

Other observations

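The counts of regions per 2-list pattern near the gene lists, their repeat with 1 gene per cluster, the comparison of X with the autosomes, and the X shares by threshold or site were chosen after the data were seen.

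Near neural progenitor genes, 12 regions had a peak in WT basal and cKO KCl only, against a median of 5 in matched random lists (percentile 99.7). Oligodendrocyte genes had 5 regions held by both WT lists alone, 1 of them near both Olig1 and Olig2 (99.1 with these counted as 1 gene), and housekeeping genes 7 against 2 (99.3). Both cKO lists alone held 6 regions near excitatory neuron genes against 2 (98.2) and 5 near housekeeping genes against 2 (98.0). Counted per gene, 6 of 102 combinations of list and pattern lay beyond the 95% random range, and 5 with 1 gene per cluster. The developmental genes (9 regions in WT basal and cKO KCl only, counted 13 times across neighbours) were the combination that was no longer beyond it. All combinations beyond the range lay above it. A chance number of 5.1 would count both ends of the range. With counts this small, even lists without any such region stayed inside it (lowest percentile 6.48, and 6.4 with 1 gene per cluster). Chance thus gives fewer than 5.1, and how many fewer was not computed.

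Near Junb, Gadd45b, Nr4a1, Npas4 and Ccn1, 6 regions had a peak in both KCl lists and in neither basal list, against a median of 2 for matched random lists (percentile 97.0). One hypothesis is that KCl raises accessibility near rapid response genes with and without Brg1. Chance among the lists and patterns could also give this count, since its percentile of 97.0 lay inside the random range. This count was thus not among the 6 pairs of 102 beyond that range. Those 6 cannot decide for or against chance here, because the number that chance gives was not computed. At regions present in all 4 lists, the mean within-list rank of 15 rapid response genes changed by 4.99 points with KCl in WT (percentile 82.3) and by -2.78 in cKO (28.1), which neither bears the hypothesis out nor excludes it, as sites absent without KCl are not among those regions. By this measure, excitatory neuron genes (0.5) and axon guidance genes (97.85), both in cKO, lay beyond the random range, 2 of 34 pairs of list and genotype where chance gives 1.7. The percentile of the count of regions in both KCl lists was 89.0 to 97.2 with other windows, thresholds and 1 gene per cluster. The rank change was not repeated under these alternatives.

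Chromosome X held a larger share of peaks in both cKO lists, 2.72% in basal (95% interval 2.51 to 2.96) and 2.88% in KCl (2.68 to 3.09), than in both WT lists, 2.14% (1.99 to 2.30) and 1.87% (1.69 to 2.06). Chance between chromosomes is not enough, since the log2 ratio of cKO to WT share was 0.48 for X and -0.10 to 0.06 for the 19 autosomes, 10.9 SD away. Nor do list lengths alone account for it, because at equal lengths the lowest cKO share exceeded the highest WT share by 0.445 percentage points. The margin was narrow, as the 95% intervals of these shares nearly touched (2.52 to 2.98% in cKO basal, 2.10 to 2.51% in WT basal). They cover counting error only. Fewer X copies among WT cultures, from the sex of the embryos, is a candidate explanation: at regions present in all 4 lists, 73.4% and 79.1% of X peaks in WT basal and WT KCl lay at the background floor against 62.5% and 48.5% in cKO basal and cKO KCl, and the excess over autosomes was at least 15.8 percentage points higher in WT. The pattern did not hold among peaks with −log10 q of at least 10, where WT basal had the highest share (2.54%, against 2.29% in cKO basal, 2.42% in cKO KCl and 1.52% in WT KCl; log2 ratio 0.21). Nor did it hold at gene ends, where WT basal and cKO basal both had 2.83% (log2 ratio 0.22), and it was clearest away from them (0.66). Chromosome Y held 5 peaks in WT basal, 4 in WT KCl, 5 in cKO basal and 4 in cKO KCl. These counts did not differ by genotype, as a difference in sex could make them do, but they are too few to decide. The sex of the embryos is not in the labels, and an effect of Brg1 loss on X stays open as untested.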
